A study of Mus musculus with 6 samples.

How the data were processed

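Small RNA was measured in mature sperm from the cauda epididymis, the storage end of the duct that carries sperm from the testis, in 8-week-old male C57BL/6 mice. Per the labels, 3 samples came from normal mice and 3 from mice made depressed by stress. Groups and replicate numbers were taken from the sample titles and disease-state labels. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, RNA was extracted with TRIzol and libraries were built with the Illumina TruSeq RNA Sample Prep Kit; library construction and sequencing were carried out at BGI, per the series design. Per the submitters' processing notes, Bowtie was used; its version is not given. The genome build, the annotation, the read filters and the counting rule are not given in the sources used here.

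The authors deposited 3 tables, for microRNAs (miRNAs), PIWI-interacting RNAs (piRNAs) and tRNA-derived small RNAs (tsRNAs), each with 1 column per sample. The deposited miRNA table holds expected counts: 92.0% of the values were whole numbers within 0.001 and the rest were fractions, as when a read that fits several mature miRNAs is split among them. The deposited piRNA table holds RPM, scaled by the authors to 1000000 per sample over the piRNA table itself. Every piRNA value was a whole multiple of the smallest value of its column (100% within 0.001), so whole reads could be recovered. The deposited tsRNA table also holds RPM, scaled by the authors to 1000000 over its own features. Its steps were fractional, and its depth was estimated from the step at which 26 to 31 low values per sample came out whole. That is a minority of the values, so the tsRNA depth is an estimate. The planned test of each class's share in the sum of the tables was set to run only if the 3 tables shared a unit and scale; they do not as deposited, so it was not run, and each table was tested by itself. Totals of the 3 tables, used as alternative library sizes, add miRNA counts, recovered piRNA reads and estimated tsRNA reads, and are estimates themselves. A change is therefore relative to the other features of the same class. Near-identical miRNAs, such as let-7 members, miR-10a and miR-10b, miR-467a and miR-467b, or the miR-465 copies, can share reads, and their single values are uncertain for that reason. Some such miRNAs stand as 1 combined feature in the table.

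Expected counts of miRNAs were rounded and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10, TMM scaling, glmQLFit and glmQLFTest). The standard error (SE) of an edgeR log2 fold change was taken as its size divided by the square root of the F statistic. Values per group are TMM-scaled CPM, counts per 1000000 reads. piRNA and tsRNA values were tested with limma 3.58.1 (trend) on log2(RPM + 1), keeping features at or above 1 RPM in at least 3 of the 6 samples. Fold changes there are on the log2(value + 1) scale, which can understate the change of features near 1 RPM. A sample at 0 can instead enlarge the change, most of all for piRNAs, where a single read is worth far more than 1 RPM. All fold changes are stress minus normal, tests are two-sided, and p-values were adjusted by Benjamini-Hochberg over the features tested in a table, with a threshold of 0.05. Differences of single shares were tested with an exact permutation test, which cannot give a p below 0.1 for 3 samples against 3.

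Before the data were examined, 18 miRNA lists were fixed, among them families, genomic clusters and markers of other cell types; 15 had at least 3 tested members. They were tested with camera in limma at a preset correlation of 0.01 on log2 CPM (prior count 2), and the tsRNAs were tested in the same way by the tRNA isotype in their names (14 of 22 isotypes had at least 3 tested features). The design, the named features and most alternatives were also fixed before the data were examined. Named miRNAs were the 10 smallest p-values in each direction among those past the threshold, the 8 most abundant, and up to 4 members of each list, those past the threshold before the most abundant. Where fewer than 5 passed in a direction, the smallest p-values of that direction were named as not having passed. The same rule with smaller numbers was used for tsRNAs and piRNAs. The design foresaw a count test only for tables of counts, so limma was the main test for piRNAs and tsRNAs. The deposited files used here do not pair piRNA identifiers with sequences or genes, so few of them are named.

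Depth was 1010203 to 3067208 reads per sample in the miRNA table, 72652 to 100913 recovered reads in the piRNA table, and an estimated 1149648 to 2756214 reads in the tsRNA table. A single piRNA read was worth up to 13.8 RPM. The tested features held at least 99.9% of the miRNA reads, 96.9% of the piRNA signal and nearly all of the tsRNA signal in each sample. Counting error alone is therefore small for abundant miRNAs, and the spread between samples sets the precision. Reads carry no molecular identifiers, so they are not independent molecules.

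The scripts were tested on simulated data with the means and library sizes of each table. In the simulated miRNA table (259 features tested), 42.4% of the features changed by 2-fold and 91.9% of those changed by 4-fold were recovered, with 2 calls among 189 unchanged features. In the simulated tsRNA table (90 features tested), 14.3% of the 2-fold and 57.1% of the 4-fold changes were recovered. In the simulated piRNA table (4408 features tested), 0% of the 4-fold changes were recovered. When the changes were placed on piRNAs at or above 100 RPM (4448 features tested), 14% of the 4-fold changes were recovered, with 0 false calls among 4348 unchanged features. The piRNA test thus has little power, and a low count of piRNA calls does not show an absence of change. In these simulated tables all features shared the same dispersion, and raised and lowered features were balanced. The rates therefore do not cover groups of unequal spread or TMM factors that separate the groups, both of which the miRNA table has. In 20 simulations with the let-7 family lowered to 0.5 times its level, camera called that family in 20, with 2 calls in 298 tests of other lists. The simulated miRNAs were drawn independently of each other. These simulations therefore cannot show how often camera calls lists falsely where members move together.

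Mature miRNA sequences from the deposited table were matched exactly to the miRNA genes of the GENCODE M21 annotation on GRCm38; all 77 named or called miRNAs matched, 17 of them at more than 1 place. Coordinates are 1-based on that build, which may not be the authors' build. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for this step and for the plots. Alternatives were RLE size factors, DESeq2 1.42.0, library sizes from the total of the 3 tables, no filter, pseudocounts of 0.1 and 10, quantile normalization, limma without the trend, a block for the replicate number, and leaving out each sample in turn. A further 3 were added after the data were seen: scaling to the total of the miRNA table without TMM, edgeR on the recovered piRNA reads, and a piRNA filter at a mean of 100 RPM. No features or samples were left out besides those below the filters.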

Results

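Small RNAs of cauda epididymal sperm were compared between 3 samples from normal mice and 3 samples from mice made depressed by stress (called normal and stress samples). The comparison asks whether a stress-induced depressed state of the father goes with a different small RNA load of the sperm. There were 778 miRNA features, 8190 piRNA features and 124 tsRNA features. Normal replicates 1 to 3 held 1083237, 1112771 and 3067208 miRNA reads, and stress replicates 1 to 3 held 1045922, 1522849 and 1010203. Between 442 and 567 miRNAs were detected per sample. The piRNA reads numbered 73594, 76199 and 86194 in the normal replicates and 100913, 76366 and 72652 in the stress replicates. The ratio of miRNA reads to estimated tsRNA reads was 0.535, 0.476 and 2.67 in the normal replicates and 0.437, 0.835 and 0.367 in the stress replicates, so normal replicate 3 stood apart.

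Samples of the same group correlated across miRNAs at r = 0.962 to 0.985, and samples of different groups at r = 0.922 to 0.972 (log2 CPM; miRNAs are not independent replicates). Normal replicate 3 correlated with stress replicates 2 and 3 (r = 0.972 and 0.969) slightly more than with normal replicates 1 and 2 (r = 0.968 and 0.966). The closest pair of samples differed with a chi-square per degree of freedom of 38.5 for miRNAs, so no column copies another, which does not show that the samples come from separate animals. On the main axis of a multidimensional scaling of the miRNAs, which held 59.1% of the variance, the normal replicates lay at −0.75, −0.48 and −0.10 and the stress replicates at 0.38, 0.48 and 0.48. The median SD of a miRNA within a group was 0.44 on the log2 scale in normal and 0.23 in stress samples.

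Several abundant members of the let-7 family, widely expressed miRNAs that repress growth and cell-cycle genes, were lower in stress than in normal sperm. let-7b-5p (−2.27 ± 0.42 SE on the log2 scale, adjusted p = 0.0074), let-7c-5p (−1.86 ± 0.25, adjusted p = 0.0032), let-7e-5p (−1.56 ± 0.29, adjusted p = 0.0074) and let-7a-5p (−1.38 ± 0.23, adjusted p = 0.0044) fell in edgeR with n = 3 per group. Normal replicate 1 carried much of the let-7b-5p change, at 135613 CPM against 49950 and 35125 CPM in normal replicates 2 and 3; without it the log2 fold change was −1.50 (adjusted p = 0.012). The level of let-7c-5p went from 186017 ± 65213 CPM (SD, n = 3) in normal to 51393 ± 7311 CPM in stress sperm. miR-669c-5p, miR-574-5p, miR-672-5p and miR-184-3p also fell, and miR-145a-5p, miR-185-5p, miR-199a-3p/miR-199b-3p and miR-20a-5p rose. Of 236 miRNAs tested, 30 passed the threshold, 24 lower and 6 higher in stress, and 76 had an unadjusted p under 0.05. On TMM-scaled values the groups did not overlap for 93 miRNAs (39.4%). Chance gives 10% for a single miRNA, but this is no null for the count. The TMM factors themselves separated the groups, and miRNAs are not independent of each other. miR-148a-3p did not overlap with TMM, but did as a share of the miRNA reads (33.6% to 50.0% in normal, 38.3% to 42.4% in stress samples).

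Shares of the miRNA reads need no scaling factor beyond the total. All let-7 members together took 30.5% ± 9.21 (SD, n = 3) of the miRNA reads in normal and 20.5% ± 2.76 in stress samples, without overlap (exact permutation p = 0.1, n = 3 per group, the smallest this design allows). The margin was thin, with normal replicate 2 at 24.0% and stress replicate 1 at 23.7%, while normal replicate 1 was at 41.0%. let-7a, let-7b, let-7c and let-7e, grouped after their calls were seen, made up 23.5% ± 9.88 in normal and 10.96% ± 1.73 in stress samples, 2.14-fold less, with normal replicate 1 alone at 34.8%. The other let-7 members stood at 6.999% ± 0.922 in normal and 9.53% ± 1.18 in stress. miR-148a-3p, the most abundant miRNA, took 43.4% ± 8.65 and 40.4% ± 2.08 (exact permutation p = 0.6, n = 3 per group). miR-10a-5p and miR-10b-5p, which lie in the Hox clusters, took 13.1% ± 0.58 and 18.6% ± 1.22. All miRNAs outside let-7 and miR-148a-3p took 26.2% ± 0.83 of the reads in normal and 39.1% ± 1.14 in stress samples.

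**Figure D1:**
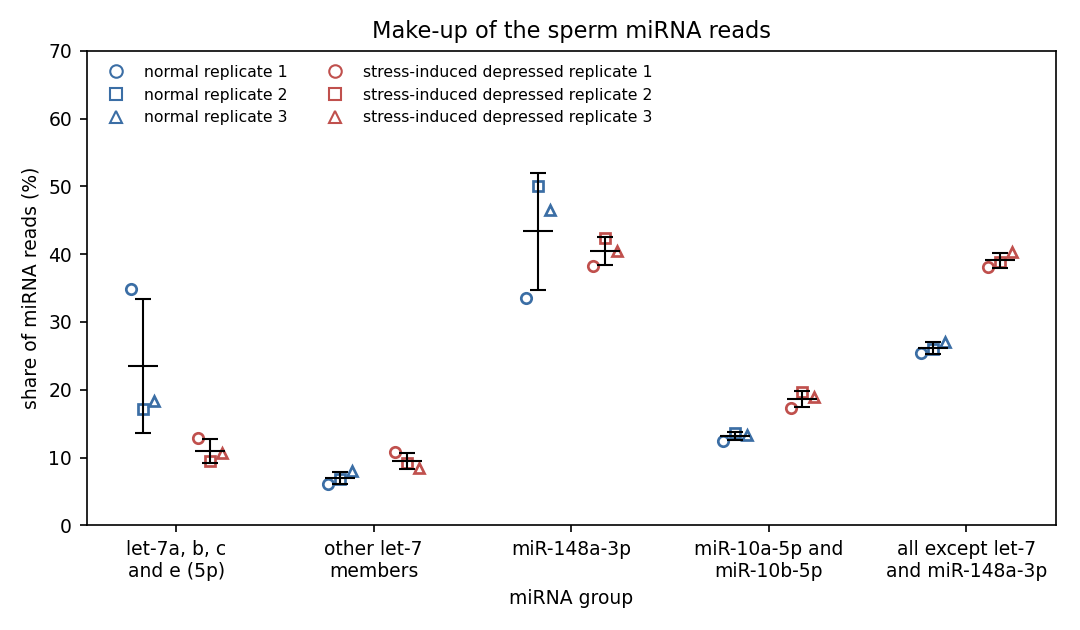
Share of the miRNA reads (percent, y axis) taken by groups of miRNAs (x axis) in each normal and stress-induced depressed sample; open symbols are samples, and the black lines are the mean with 1 SD (n = 3). let-7a, b, c and e lie at 17.1% to 34.8% in normal and at 9.42% to 12.8% in stress samples, and miR-148a-3p overlaps between the groups.

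Of 12 tested let-7 features, 5 fell, 0 rose and 7 did not pass (6 fell when adjusted over the list alone). The fifth that fell was let-7d-3p, named after its values were seen (−1.14 ± 0.26, adjusted p = 0.016 in edgeR); it was not called without stress replicate 1, 2 or 3 (adjusted p = 0.053, 0.068 and 0.10). let-7g-5p (0.45 ± 0.25, adjusted p = 0.23) and let-7f-5p (−0.47 ± 0.20, adjusted p = 0.14) did not pass in edgeR. The family's median was −0.80, and camera in limma called it lower (adjusted p = 0.012 over 15 lists). This call is lost with an estimated correlation (adjusted p = 0.67 with an estimated correlation). let-7c-5p comes from chromosome 16, 77599672 to 77599693, in an intron of the noncoding gene Mir99ahg, and from chromosome 15, 85706616 to 85706637, in an exon of the noncoding gene Lncppara. let-7b-5p lies in an exon of the same Lncppara (chromosome 15, 85707325 to 85707346). let-7e-5p lies in an intron of Spaca6, a gene for a sperm membrane protein, on chromosome 17 (17830366 to 17830387). let-7a-5p matched Mirlet7a-1 on chromosome 13 (48538239 to 48538260, in an exon of the noncoding 6720427I07Rik) and Mirlet7a-2 on chromosome 9 (41536732 to 41536753, intronic in noncoding transcripts).

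Outside let-7, miR-669c-5p fell from 2379 ± 1689 CPM (SD, n = 3) to 249.6 ± 50.6 CPM (log2 fold change −3.25 ± 0.50 SE). It lies in an intron of Sfmbt2 on chromosome 2 (10509319 to 10509340), amid a large miRNA cluster. Normal replicate 1 was at 4229 CPM, and without it the log2 fold change of miR-669c-5p was −2.57. miR-574-5p fell from 384.9 ± 395.6 to 39.6 ± 1.98 CPM (−3.27 ± 0.64), with normal replicate 1 alone at 839.8 CPM, and at −2.003 on the log2 scale without that sample; it lies in an intron of Fam114a1 on chromosome 5 (64970328 to 64970350). miR-672-5p, in an intron of Nexmif on the X chromosome (104116228 to 104116250), fell by 2.04 on the log2 scale. miR-184-3p (chromosome 9, 89802263 to 89802284) fell from 1983 ± 639.1 to 560.8 ± 33.5 CPM. miR-423-5p, in an intron of Nsrp1, fell by 1.51 on the log2 scale, and miR-485-5p, in an exon of the noncoding Mirg, fell by 1.94 on that scale. In edgeR, the adjusted p-values of these 6 miRNAs lay between 0.0044 and 0.0094, and each was lower in 3 of 3 stress samples than in every normal sample.

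Among the 6 miRNAs that rose, miR-145a-5p, a miRNA of smooth muscle on chromosome 18 (61647866 to 61647888), rose from 15.9 ± 6.72 CPM (SD, n = 3) to 60.2 ± 3.72 CPM (1.96 ± 0.35 SE). miR-185-5p, in an intron of Tango2 on chromosome 16 (18327438 to 18327459), rose from 61.7 ± 4.13 to 148.0 ± 6.74 CPM (1.26 ± 0.25). miR-199a-3p/miR-199b-3p, which has 3 genomic copies, rose from 182.0 ± 56.0 to 447.1 ± 48.4 CPM (1.29 ± 0.30). miR-20a-5p, in the noncoding Mir17hg on chromosome 14 (115044183 to 115044205), rose from 66.2 ± 21.1 to 154.7 ± 3.48 CPM (1.24 ± 0.30). miR-1291, in an intron of Kansl2, rose by 1.68 ± 0.47 on the log2 scale. miR-677-5p rose as well, but was at 0, 1.32 and 0.380 CPM in the normal replicates, below the level of 3 reads. In edgeR, the adjusted p-values of these 6 miRNAs lay between 0.0072 and 0.039, with 3 of 3 stress samples above every normal sample. The call of miR-199a-3p/miR-199b-3p was lost without stress replicate 3 (adjusted p = 0.053), that of miR-20a-5p without stress replicate 2 or 3 (adjusted p = 0.059 and 0.053), and that of miR-1291 without normal replicate 1 or 2 or stress replicate 3 (adjusted p = 0.11, 0.071 and 0.088); without normal replicate 3 miR-1291 was at 2.31.

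**Figure D2:**
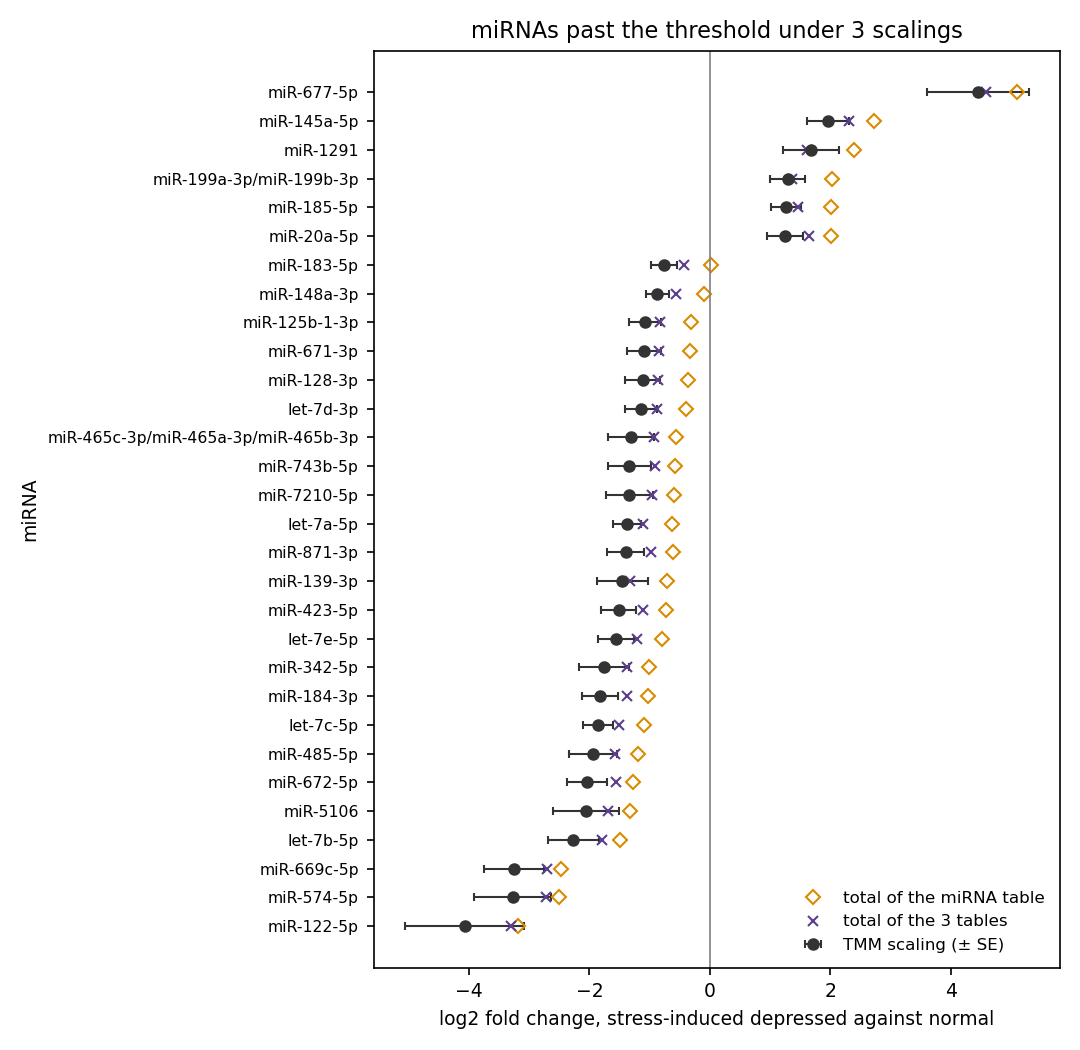
Log2 fold change (x axis, stress-induced depressed against normal) of the 30 miRNAs past the threshold (y axis) under TMM scaling (points with SE), scaling to the total of the miRNA table (diamonds) and scaling to the total of the 3 tables (crosses). The median of all miRNAs is 0.0006 with TMM, 0.76 with the miRNA total and 0.25 with the total of the 3 tables. Both totals thus move fold changes upward, and that the 6 higher miRNAs stay above 0 is no test of them. Of the 24 lower ones only miR-183-5p, named after its values were seen, crosses 0 (0.02 with the miRNA total).

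The X-linked testis cluster, a group of miRNAs of male germ cells, had 3 members that fell, 0 that rose and 12 that did not pass (4 fell when adjusted over the list alone). They were miR-871-3p (−1.40 ± 0.31), miR-743b-5p (−1.34 ± 0.36) and the combined miR-465a/b/c-3p feature (−1.31 ± 0.38), while miR-881-3p, at −0.91 ± 0.29, did not pass (adjusted p = 0.033 without normal replicate 3). miR-871-3p was not called without stress replicate 2 or 3 (adjusted p = 0.059 and 0.053), miR-743b-5p not without normal replicate 1 or 2 or stress replicate 1 or 3 (adjusted p = 0.11, 0.078, 0.086 and 0.10), and miR-465a/b/c-3p not without normal replicate 1 or 2 or stress replicate 2 or 3 (adjusted p = 0.11, 0.065, 0.13 and 0.14). The cluster as a whole was not called (median −0.59, camera adjusted p = 0.24), and scaled to the miRNA total its median was 0.18 with 4 members higher. That median lay below the median of all miRNAs with the same scaling (0.76). The direction in camera was still downward there, without a call (adjusted p = 0.28). The list for miR-34 and miR-449 in male germ cells had 0 of 4 tested features past the threshold (median −0.04, mean 0.07, camera adjusted p = 0.85), with miR-34c-5p at 0.13 ± 0.34. These 4 features are the arms of miR-34b and miR-34c, so no miR-449 and no miR-34a was tested. Of 11 miRNAs reported elsewhere as stress-sensitive in sperm, 1 fell (miR-672-5p) and 10 did not pass, with miR-375-3p at −0.57 ± 0.23 and miR-30a-5p at 0.62 ± 0.27 (median −0.15, adjusted p = 0.45). In the Dlk1-Dio3 imprinted cluster 1 of 9 members fell, miR-485-5p (median −0.50, adjusted p = 0.54). In the Sfmbt2 intron cluster 1 of 8 fell, miR-669c-5p, while the list's median was 0.18, its mean −0.13 and its test upward (adjusted p = 0.67). In the miR-17-92 cluster and its paralogs 1 of 7 rose, miR-20a-5p (2 when adjusted over the list alone, median 0.45, adjusted p = 0.20). No member passed in the miR-30 family (9 tested, median 0.26, adjusted p = 0.40), the miR-181 family (3 tested, median 0.53, adjusted p = 0.24) or the miR-10/99/100 family (8 tested, median −0.08, mean 0.01, adjusted p = 0.85).

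Markers of cells other than sperm were tested as 5 lists. Of 8 stromal, smooth muscle and endothelial markers, 2 rose (miR-145a-5p and miR-199a-3p/miR-199b-3p), 6 did not pass and 3 rose when adjusted over the list alone. The 8 are features with 5 different numbers in their miRNA names, with arms and close copies counted apart. miR-143-3p was at 0.49 ± 0.28 and miR-126a-3p at 0.55 ± 0.28. All 8 had positive fold changes (median 0.52), and camera called the list higher (adjusted p = 0.019), but not with an estimated correlation (adjusted p = 0.51 with an estimated correlation), nor without normal replicate 3 (adjusted p = 0.11) or scaled to the miRNA total (adjusted p = 0.077). Red blood cell markers had a median of −1.47 (−0.65 without normal replicate 1) with 0 of 3 past the threshold (2 lower when adjusted over the list alone, camera adjusted p = 0.34); miR-486a/b-5p was at −1.47 ± 0.53 (called without normal replicate 3 or stress replicate 1, adjusted p = 0.020 and 0.014) and miR-451a at −0.18 ± 0.58 (−0.77 without stress replicate 2). Of 8 epithelial markers, which the epididymal lining expresses, 0 passed (median 0.41, adjusted p = 0.40), with miR-200c-3p at 0.38 ± 0.22 and miR-200b-3p at 0.07 ± 0.21. Of 6 leukocyte markers 0 passed (2 higher when adjusted over the list alone, median 0.44, adjusted p = 0.40), with miR-146a-5p at 0.87 ± 0.29 (called without normal replicate 3, adjusted p = 0.020). Of 3 neural markers 1 fell, miR-128-3p (−1.12 ± 0.30; median −0.34, adjusted p = 0.65), which was not called without normal replicate 1 or stress replicate 1, 2 or 3 (adjusted p = 0.060, 0.053, 0.13 and 0.10). Scaled to the miRNA total, 6 of the 8 stromal, 6 of the 8 epithelial and 4 of the 6 leukocyte markers were called higher. With that scaling so were 96 of all 236 miRNAs (median of all 0.76) and 7 of the 9 tested miR-30 family members. camera called none of these marker lists there (adjusted p = 0.077 stromal, 0.28 epithelial and 0.63 leukocyte). These counts are therefore no sign of RNA from other cells. The miR-29 family and the muscle markers had 2 tested members each and the miR-290-295 cluster 0, so they were not tested as lists.

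The balance of lower and higher calls depended on the scaling, because the TMM factors were 0.772 ± 0.088 in normal and 1.303 ± 0.068 in stress samples (exact permutation p = 0.1, n = 3, the smallest possible). Scaled to the total of the miRNA table the median of all miRNAs moved to 0.76 and edgeR called 96 higher and 10 lower, scaled to the total of the 3 tables the median was 0.25 and 3 were higher and 3 lower, and RLE and DESeq2 gave 16 higher with 28 lower and 17 higher with 30 lower. With the miRNA total, let-7a, let-7b, let-7c and let-7e, miR-669c-5p, miR-574-5p, miR-672-5p and miR-184-3p were still called lower and the let-7 list was still called (adjusted p = 0.014, with 4 members lower, 2 higher and a median of −0.07; adjusted p = 0.65 with an estimated correlation), while miR-148a-3p went from −0.87 to −0.10 and was not called, and miR-10a-5p and miR-10b-5p, at −0.33 and −0.18 with TMM, were called higher at 0.44 and 0.58. With the total of the 3 tables, 4 of the 30 calls were kept, miR-669c-5p, miR-574-5p and miR-122-5p (named after its values were seen) lower and miR-677-5p higher. All let-7 calls were lost there, let-7c-5p at −1.51 (adjusted p = 0.22), let-7b-5p at −1.79 (adjusted p = 0.084), let-7e-5p at −1.21 (adjusted p = 0.48), let-7a-5p at −1.11 (adjusted p = 0.55) and let-7d-3p at −0.87 (adjusted p = 0.76), while the let-7 list was still called (adjusted p = 0.028, but adjusted p = 0.95 with an estimated correlation). camera compares the members of a list with the other miRNAs, and a change of library size moves all miRNAs about alike. Its let-7 call was therefore nearly bound to stay, and does not show that the let-7 decrease holds under these scalings. The log2 fold change fell with the G content of the mature sequence across the 236 miRNAs (Spearman rho = −0.28, permutation p = 1e-04, the smallest the permutations can give). The permutations treat related miRNAs, such as let-7 members, as independent, so this p may be too small. After a correction for G and GC content let-7c-5p was at −1.38 ± 0.20 and let-7b-5p at −1.58 ± 0.34. Without normal replicate 3 the calls numbered 55, and without stress replicate 3 they numbered 17; 14 calls (11 lower, 3 higher) were kept whichever sample was left out.

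piRNAs, which guard the germline against transposons and come largely from the testis, differed past the threshold for 1 of 3152 tested features. mmu_piR_032015 fell from 9230 ± 3487 RPM (SD, n = 3) in normal to 1414 ± 376.9 RPM in stress samples (log2 fold change −2.66 ± 0.36 SE, limma adjusted p = 0.025), lower in 3 of 3 stress samples than in every normal sample. Next to it, mmu_piR_027735 was at −2.58 ± 0.48, mmu_piR_000705 at 1.70 ± 0.33 and mmu_piR_005109 at 1.29 ± 0.32, and these did not pass in limma (adjusted p = 0.19, 0.19 and 0.20). The most abundant piRNA, mmu_piR_032974, was at 290035 ± 82446 RPM in normal and 311315 ± 43733 RPM in stress samples and did not pass (0.14 ± 0.47). The files do not pair these identifiers with sequences or genes.

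Replicates were less alike for piRNAs than for miRNAs, with r = 0.437 to 0.488 across piRNAs within a group and 0.386 to 0.451 between groups. In limma, 340 piRNAs had an unadjusted p under 0.05. The groups did not overlap for 516 piRNAs (16.4%). Chance gives 10% for a single piRNA, which is no null for this count because the fold changes were shifted as a whole (median −0.38). edgeR on the whole reads, recovered for 100% of the values within 0.001, called 18 of 378 tested piRNAs, 14 higher and 4 lower, among them mmu_piR_032015 (−2.16) and mmu_piR_000705 (2.34). The limma count ranged from 0 with a pseudocount of 0.1 to 117 without the trend, where mmu_piR_032015 was not called, and it was 2 without normal replicate 3, 2 without stress replicate 1 and 3 without stress replicate 2, where mmu_piR_027735 (−2.89) and mmu_piR_000705 (1.93) passed as well. The median log2 fold change of all tested piRNAs was −0.38 and moved to 0.00 with quantile normalization; over the 378 piRNAs tested in edgeR it was −0.01.

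tsRNAs, fragments cut from mature tRNAs and abundant in sperm from the epididymis, differed in their main isotypes by less than the spread of the samples. Fragments from the 5′ end made up 99.9% ± 0.052 (SD, n = 3) of the tsRNA signal in normal and 99.8% ± 0.048 in stress samples. tRNA-Glu fragments took 64.6% ± 2.51 and 64.1% ± 2.22, and tRNA-Gly fragments 31.2% ± 1.32 and 32.0% ± 1.68 (exact permutation p = 0.9 and 0.7, n = 3 per group). The most abundant fragment, the 5′ end of tRNA-Glu-CTC, had a log2 fold change of −0.02 (95% interval −0.12 to 0.07), and the 5′ end of tRNA-Gly-GCC one of 0.03 (−0.09 to 0.16). The 5′ ends of tRNA-Glu-TTC and tRNA-Gly-CCC were at 0.07 ± 0.11 SE and 0.04 ± 0.13. Because tRNA-Glu and tRNA-Gly nearly fill a table scaled to its own total, their shares can hardly move except against each other. These values therefore do not show that the amounts of these fragments were unchanged.

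**Figure D3:**
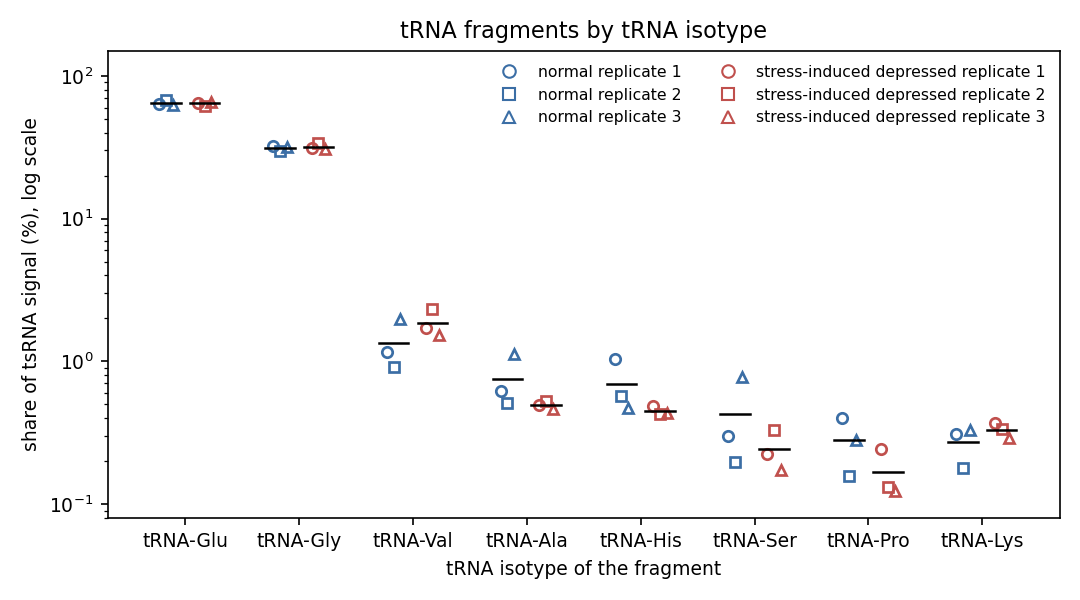
Share of the tsRNA signal (percent, logarithmic y axis) by the tRNA isotype of the fragment (x axis) for the 8 most abundant isotypes; open symbols are samples and black lines group means (n = 3). tRNA-Glu lies at 61.6% to 67.5% and tRNA-Gly at 29.7% to 33.9% over the 6 samples.

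limma called 0 of 87 tested tsRNAs, 8 had an unadjusted p under 0.05, and limma without the trend also called 0. The smallest p-values belonged to low features, the 5′ end of tRNA-Arg-CCG (2.08 ± 0.70 SE, 4.12 ± 3.68 against 14.8 ± 2.80 RPM, and 1.14 without normal replicate 3, which was at 0 RPM), the 3′ end of tRNA-Glu-CTC (1.98 ± 0.74, 11.3 ± 6.45 against 46.9 ± 20.5 RPM) and the 3′ end of tRNA-Thr-AGT (1.82 ± 0.69), each with an adjusted p of 0.26 in limma. Those with the smallest p-values among lower features were the 5′ end of tRNA-Ala-TGC (−1.01 ± 0.42), the CCA end of tRNA-Lys-CTT (−1.61 ± 0.70) and the 5′ end of tRNA-Leu-TAG (−1.26 ± 0.59), and they did not pass. The last was at −0.37 without normal replicate 1 and at −1.88 without stress replicate 2. The 5′ end of tRNA-Val-CAC was at 0.52 ± 0.23 and that of tRNA-His-GTG at −0.55 ± 0.29. By isotype, camera called 0 of 14; tRNA-Pro (median −0.52), tRNA-Glu (0.64) and tRNA-Ser (−0.35) had unadjusted p-values of 0.016, 0.027 and 0.039 and an adjusted p of 0.18 each in limma. Quantile normalization gave 1 call (tRNA-Glu-CTC_3_end), and leaving out normal replicate 3 gave 2 (tRNA-Glu-CTC_3_end at 2.38 and tRNA-Val-CAC_5_end at 0.83).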

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

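Scaling to the miRNA total, edgeR on recovered piRNA reads and the piRNA filter at a mean of 100 RPM were chosen after seeing the data; the other alternatives were planned. Against 30 miRNA calls with TMM in edgeR, the counts were 44 with RLE (30 kept), 47 with DESeq2 (29 kept), 49 without a filter (28 kept), 6 with the total of the 3 tables (4 kept), 106 with the miRNA total (16 kept) and 17 to 55 when single samples were left out. With the miRNA total miR-10a-5p (0.44) and miR-10b-5p (0.58) reversed and were called higher; this setting leaves out factors that differ between the groups, which moves the median fold change to 0.76. Another 13 named miRNAs, called in neither setting, changed sign there, and 8 did with the total of the 3 tables. The causes of the other differences were not tested. The piRNA calls numbered 1 in the planned test, 3 with quantile normalization, 117 without the trend, 17 without a filter, 0 and 14 with pseudocounts of 0.1 and 10, 18 in edgeR, 39 with the filter at 100 RPM (6 higher, 33 lower, around a median of all tested piRNAs of −0.64, while edgeR with TMM gave 14 higher and 4 lower around −0.01) and 1 to 3 when single samples were left out. The tsRNA calls numbered 0 in the planned test, 1 with quantile normalization and 0 to 2 when single samples were left out. Lists called numbered 2 with the preset correlation, 0 with an estimated one and 1 to 2 when single samples were left out. With fry, which tests whether members move one way without comparison with other miRNAs, they numbered 3, adding the stress-sensitive list. Over these settings and the replicate block, all with TMM, the adjusted p ranged from 0.0031 to 0.67 for let-7. For the stromal list it ranged from 0.0071 to 0.51. With the total of the 3 tables and an estimated correlation, camera put both lists at an adjusted p of 0.95. Isotype calls were 0 in every setting run.

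The labels give no pairing by replicate number, and none was clear in the values. Same-numbered deviations correlated at 0.11, −0.21 and 0.12 for miRNAs and at 0.003, −0.008 and 0.026 for piRNAs. For tsRNAs they correlated at 0.19, −0.36 and −0.23, and not every sample correlated best with its own number. With 3 samples per group these correlations cannot exclude a pairing. With the replicate block the calls were 28 miRNAs (24 kept), 5 piRNAs, 0 tsRNAs, 2 lists and 0 isotypes. Library sizes from the 3 tables, RLE and DESeq2 need counts and were not run for piRNAs and tsRNAs, and pseudocounts were not run for miRNAs; the share of each class in the sum of the tables was not run at all. Depth limits the piRNAs most, since 1 read is worth up to 13.8 RPM.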

Other observations

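In this part the test of scaling was chosen after the TMM factors had been seen; the tests of sequence composition, length and other cell types were set down before their values were computed, but after the list of called miRNAs had been seen. The tests over samples for the marker lists were added after the fold changes had been seen.

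Some miRNAs of other tissues varied widely between samples. miR-122-5p, the main miRNA of liver, was at 2418 CPM in normal replicate 2, at 343.3 and 124.5 CPM in normal replicates 1 and 3, and at 109.9, 28.0 and 33.8 CPM in the stress replicates (edgeR log2 fold change −4.07 ± 0.99 SE, adjusted p = 0.022); it was named after its values were seen, and without normal replicate 2 it was at −2.01 and not called (adjusted p = 0.094); without stress replicate 1 it was at −4.88. The muscle miRNA miR-1a-3p reached 3497 CPM in stress replicate 1 and lay between 128.3 and 492.3 CPM in the other samples, while miR-206-3p, also of muscle, was at 126.8, 321.2 and 8.35 CPM in the normal replicates and 56.4, 5.29 and 10.1 CPM in the stress replicates. Neither muscle miRNA passed in edgeR with TMM and all samples (adjusted p = 0.11 and 0.12). Scaled to the miRNA total, edgeR called miR-1a-3p higher (3.22, adjusted p = 0.020) but not miR-206-3p (−1.80, adjusted p = 0.16). Over 12 alternatives in edgeR or DESeq2 the adjusted p of miR-1a-3p ranged from 1.9e-12 to 0.87. That of miR-206-3p ranged from 8.7e-10 to 0.42. miR-1a-3p was called higher without stress replicate 2 or 3 (adjusted p = 0.041 and 0.021) but was at 0.15 without stress replicate 1, and miR-206-3p was called lower without normal replicate 3 or stress replicate 1 (adjusted p = 0.020 and 0.0059) but was at −1.43 without normal replicate 2. The miR-29 family members were at 0.29 ± 0.28 (miR-29a-3p) and −0.14 ± 0.44 (miR-29b-3p).

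The called miRNAs, let-7a, let-7b, let-7c and let-7e among them, differ in sequence from the rest: the median G content was 38.6% for the 24 lower ones, 22.9% for the 6 higher ones and 27.3% for all 236. Within let-7, let-7b-5p (45.5% G) was at −2.27 and let-7g-5p (31.8% G) at 0.45, but let-7d-3p (13.6% G) was at −1.14, against this order. A linear correction for G and GC content in each library kept 28 of the 30 calls and added others (48 in all), which argues against this trend as the whole cause, although let-7c-5p went from −1.86 ± 0.25 to −1.38 ± 0.20, and 4 kept calls shrank by over 1.5-fold: let-7b-5p (−2.27 ± 0.42 to −1.58 ± 0.34), miR-574-5p (−3.27 ± 0.64 to −2.46 ± 0.54), miR-423-5p (−1.51 ± 0.30 to −0.88 ± 0.25) and miR-672-5p (−2.04 ± 0.34 to −1.42 ± 0.28). miR-139-3p (−1.45 ± 0.42 to −0.81 ± 0.44) and miR-125b-1-3p (−1.07 ± 0.27 to −0.54 ± 0.28) lost their calls because their fold changes shrank (both were named after their values were seen). A correction for mature length kept 23 of 30. Of the 7 lost, 6 moved little and ended just above the threshold (adjusted p = 0.054 to 0.055): miR-465a/b/c-3p (−1.31 ± 0.38 to −1.31 ± 0.39), miR-743b-5p (−1.34 ± 0.36 to −1.24 ± 0.38), miR-128-3p (−1.12 ± 0.30 to −1.03 ± 0.32), miR-183-5p (−0.76 ± 0.22 to −0.71 ± 0.21), miR-139-3p (−1.45 ± 0.42 to −1.40 ± 0.43) and miR-671-3p (−1.10 ± 0.28 to −0.98 ± 0.29). The seventh, miR-1291, shrank from 1.68 ± 0.47 to 1.298 ± 0.48 (adjusted p = 0.079). miR-183-5p and miR-671-3p were named after their values were seen. Length was not related to the fold change across miRNAs (rho = 0.05, permutation p = 0.43). Over the 3 properties tested, the adjusted permutation p for G was 3e-04. These permutations treat related miRNAs as independent. A part played by a composition-dependent library step may remain. Slopes on G content were taken on each miRNA's log2 level minus its mean over the 6 samples. Per 10% G they were 0.26 and 0.26 in normal replicates 1 and 2 but −0.01 in normal replicate 3. In the stress replicates they were −0.15, −0.23 and −0.12. Such slopes balance out over the samples by construction. Only their differences between samples count, and they show no negative trend of the stress samples on their own. Stress itself stays open, untested apart from the groups.

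More miRNAs were lower than higher in stress samples (24 against 6). The 10 most abundant miRNAs took 87.5% ± 0.86 (SD, n = 3) of the reads in normal and 80.7% ± 1.002 in stress samples. Whether a few miRNAs that take most of the reads set this balance through the scaling cannot be told apart from a change in stress samples. With the miRNA total 10 of the 24 lower calls were still called lower, but this decides nothing, because the TMM factors already separated the groups and leaving them out moves all fold changes upward (median 0.76). Of the 24, only 3 were still called with the total of the 3 tables, while let-7c-5p, let-7b-5p and miR-184-3p were at −1.51, −1.79 and −1.38 there. RLE and DESeq2 kept 24 and 23 of the 24 and gave 28 lower with 16 higher and 30 lower with 17 higher. The tables hold no external standard to settle which scaling tracks molecules per sperm.

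All 8 stromal features had positive fold changes, with 2 past the threshold, but they come from only 5 miRNA numbers. The camera call of this list is lost with an estimated correlation (adjusted p = 0.51). Of 15 members of the X-linked testis cluster, 3 were called lower (list median −0.59). The other germ-cell list, in which only miR-34b and miR-34c were tested, had a median of −0.04 and a mean of 0.07. More RNA from other cells could produce such values, and whether it did cannot be told apart here. The epithelial and leukocyte medians (0.41 and 0.44) go with it, and the red blood cell median (−1.47, but −0.65 without normal replicate 1) goes against it, as does the neural median (−0.34). The red blood cell list was to count against a general rise of such RNA if its upper quartile lay below 0, and the quartile was −0.83, but this bound was too weak: the list holds 3 features, 2 of them arms of miR-486, and with these averaged first its difference between the groups was −1.01 ± 0.70 SE (exact permutation p = 0.3, n = 3 per group), with samples that overlap. The epithelial (0.49 ± 0.22 SE, p = 0.2), leukocyte (0.52 ± 0.37, p = 0.2) and neural (−0.51 ± 0.25, p = 0.2) lists overlap in the same exact permutation test (n = 3 per group), and the stromal list does not (0.75 ± 0.08, p = 0.1, the smallest possible). Set against the stromal list per sample, the red blood cell difference was −1.77 ± 0.71 SE without overlap (exact permutation p = 0.1). These 2 lists were paired after their fold changes were seen, and the stromal list alone already separates the groups. This contrast therefore cannot count against a general rise. The red blood cell list also rests on 2 miRNAs, of which miR-451a was at −0.18 ± 0.58 (−0.77 without stress replicate 2). The most abundant stromal marker, miR-143-3p, was at 4715 ± 1682 CPM (SD, n = 3) in normal and 6641 ± 489.3 CPM in stress samples. A change in stromal or smooth muscle cells alone stays open too, and the epididymal wall holds both epithelial and smooth muscle cells, so these lists do not separate carry-over of tissue from RNA taken up by sperm in the duct. No purification of the sperm beyond extraction from the cauda is given in the sources used here.

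Splitting the 6 samples into 3 and 3 gives 10 splits, too few for a share under 0.05. The real split gave 30 miRNA calls and the highest other split 1; for piRNAs the counts were 1 and 0, for tsRNAs 0 and 0, for miRNA lists 2 and 1, and for tRNA isotypes 0 and 2.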
